A study of Caenorhabditis elegans with 4 samples.

How the data were processed

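Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mixed-sex Caenorhabditis elegans embryos grown at 20 °C, from a strain carrying a MED-1 transgene tagged with green fluorescent protein (GFP) in an unc-119 mutant background rescued by the transgene's unc-119 copy. MED-1 is a GATA-type zinc finger transcription factor of the early embryonic mesendoderm. Per the labels' protocols, worms were fixed with formaldehyde and chromatin was sonicated. Part of the lysate was kept as input DNA, and the rest was precipitated with an antibody to GFP. Peaks at sequences that the transgene carries, med-1 and unc-119 among them, may come from extra copies of that DNA and not from binding, and such peaks could not be picked out here, since genes were not placed on this build. The labels give 4 samples, 2 ChIP samples and 2 inputs, numbered 1 and 2 in each group. The sample titles carry the tag MIDEMB, while the stage label says embryo. How the tag relates to the early stage at which MED-1 acts was not examined. Nothing in the labels says whether the numbers mark separate cultures, so the agreement between the replicates measures the spread between these samples only, which may be technical.

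The data used here are 3 lists of binding sites, 1 for each ChIP replicate and 1 named as combined. Per the file headers, the authors' lists are PeakSeq binding sites on coordinates of the WormBase WS180 genome build. PeakSeq is a peak caller that scores regions of a ChIP library against a control library. The deposited value of each peak is a q-value, per the file headers, and it is each peak's own value as the authors' caller gave it. The largest q-value was 6.06e-05 in replicate 1, 7.1e-05 in replicate 2 and 7.83e-05 in the combined list. The aligner, the PeakSeq version, the threshold, the control library used for each list and the way the replicates were combined are not given in the sources used here. The lists hold no read counts, heights or summits, so sequencing depth is unknown and no counting interval for a peak could be given. The q-values depend on depth, and a deeper library gives more and smaller q-values for the same binding. Input values were not analysed here, so no background level stands beside the ChIP peaks.

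In the list of replicate 1, 209 of 212 sites appeared as pairs of overlapping lines, which made 421 lines. Lines sharing at least 1 bp were merged into 1 site spanning both, with the smaller q-value. The other lists had no overlapping lines. Peak strength was expressed as −log10 of the deposited q-value. Medians of groups of peaks were compared within a list. Shared pairs, and combined peaks against the sum of the replicate values, were compared between lists, whose depths may differ. Coordinates are 1-based and inclusive.

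Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and plots were drawn with matplotlib 3.10.9. Peaks were called shared when they overlapped by at least 1 bp. Overlap was compared with 10000 shuffles of the replicate 1 sites within their chromosomes, keeping widths, and the one-sided permutation p cannot fall below 1e-04. Strengths of shared pairs were compared by Spearman and Pearson correlation, and medians of shared and single sites by their difference, each with 100000 permutations, two-sided, so that p cannot fall below 1e-05. Shares carry 95% exact (Clopper-Pearson) binomial intervals. They cover counting error only and treat peaks as independent. Peaks per chromosome were compared with the chromosome's share of the genome by a two-sided exact binomial test with Benjamini-Hochberg adjustment over 6 chromosomes. Chromosome lengths of WS180 were not used here. Each chromosome was taken to run from base 1 to the highest peak end in any list, 99.4 Mb in all, which understates the true lengths by an unknown amount. The central part of a chromosome is the middle 50% of that span.

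The tests were run first on simulated lists. With no shared site, 1 of 40 simulated pairs of replicate lists with the real widths was called. With 100 planted shared sites among 212, 100 were counted. A simulated correlation of 0.7 came back as a mean r of 0.689 over 50 runs, and a simulated median difference of 1 as a mean of 1.035 (SD 0.19) over 50 runs. These 2 checks were first run as single draws, which strayed further, and were repeated 50 times later. They drew normally distributed values, while the real −log10 q values are cut at a threshold and include an extreme region. They therefore check the calculation and not its behaviour on such values. For the chromosome test on 599 peaks, the weight of chromosome III was raised 1.5 times before all weights were rescaled. Its simulated share thus rose by somewhat less than 1.5 times. It was called in 74 of 100 simulated lists, so smaller imbalances can be missed. The simulated peaks were drawn independently, while some real peaks lie close together, so this rate may not hold for the real list. For the central part, 1 of 20 even lists was called.

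Before the data were examined, the main comparisons, their tests, a first set of alternatives and the rule for named sites were fixed. The rule named the 15 strongest combined peaks that overlap peaks of both replicates, and sites by gene where an annotation of the files' build allowed it. The reference table of genes was of another build (WBcel235), and coordinates of different builds were not mixed. The comparisons fixed for promoters, annotation classes, gene lists, small RNA genes and sequence motifs, including the MED-1 site, and a shuffle over promoter windows were therefore not run, and sites are named by position. Alternatives fixed beforehand covered the overlap rule, the strength threshold, list length, the strongest pairs, the shuffle and single replicate lists. Those chosen after seeing the data were the unmerged lines of replicate 1, the lowest significance of merged lines, leaving out the strongest region on chromosome I, peaks with a replicate match, merging of near peaks, a minimum peak width and the chromosome span from the lowest peak start. The split of the central share by replicate match was chosen then too.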

Results

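Binding of MED-1, tagged with GFP, was mapped by ChIP-seq in whole C. elegans embryos in 2 replicate immunoprecipitations. The list of replicate 1 held 212 sites and that of replicate 2 held 258. The combined list held 599 peaks. Median peak width was 310 bp in replicate 1, 296.5 bp in replicate 2 and 311 bp in the combined list. The sites of replicate 1 covered 79.9 kb, those of replicate 2 covered 91.7 kb and the combined peaks covered 232 kb of the 6 chromosomes. Each list carries the authors' PeakSeq q-value as the only measure of strength, and the depth behind it is unknown.

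The first comparison asked how far the binding sites of the replicates coincided. Of the 212 sites of replicate 1, 167 overlapped a site of replicate 2, which is 78.8% (95% exact interval 72.6 to 84.1%). These were 64.7% of the 258 sites of replicate 2 (58.6 to 70.6%). The shared sites lay almost on top of one another, with midpoints a median of 17 bp apart. They made up 55.1% of the 303 sites found in either list. Shuffling the sites of replicate 1 within their chromosomes gave a mean of 0.418 shared sites and at most 4 in 10000 shuffles. The overlap was thus above that of random placement (one-sided permutation p = 1e-04, the smallest the shuffles can give). Random placement takes no account of where a ChIP library gives background signal, so the test cannot tell shared binding from shared background. Ends were identical in 1 of the 167 pairs, so the lists are not copies of one another.

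Stronger sites were found again more often. In the strongest 25% of replicate 1, 51 of 53 sites had a partner in replicate 2 (96.2%, exact interval 87.0 to 99.5%), against 28 of 53 in the weakest 25% (52.8%, 38.6 to 66.7%). In replicate 2 the strongest 25% had 62 of 65 sites with a partner (95.4%, 87.1 to 99.0%) and the weakest 18 of 64 (28.1%, 17.6 to 40.8%). Median −log10 q was 7.29 for the 167 shared and 5.02 for the 45 single sites of replicate 1, a difference of 2.27 (two-sided permutation p = 0.00014, adjusted over both lists 0.00014). In replicate 2 the medians were 7.40 for shared and 4.91 for the 91 single sites, a difference of 2.49 (permutation p = 1e-05, adjusted 2e-05). The strongest single sites still reached −log10 q of 9.55 in replicate 1 and 9.80 in replicate 2. Both lists hold only sites past a threshold, so a site near it in either list can more easily miss it in the other. The differences between shared and single sites therefore describe the lists and are no independent support for the shared sites.

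Across the 167 shared pairs, strength in one replicate followed strength in the other. Spearman's rho was 0.64 and Pearson's r was 0.98 on −log10 q (two-sided permutation p = 1e-05 for each, the smallest the permutations can give). Without the 2 sites farthest from the median of replicate 1, rho was 0.63 and r was 0.81 (permutation p = 1e-05 for each). Without the 10 strongest pairs, an alternative fixed beforehand, rho was 0.57 and r was 0.72 (permutation p = 1e-05 for each). These are correlations across sites, which are not independent replicates, and only sites past both thresholds enter them.

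**Figure D1:**
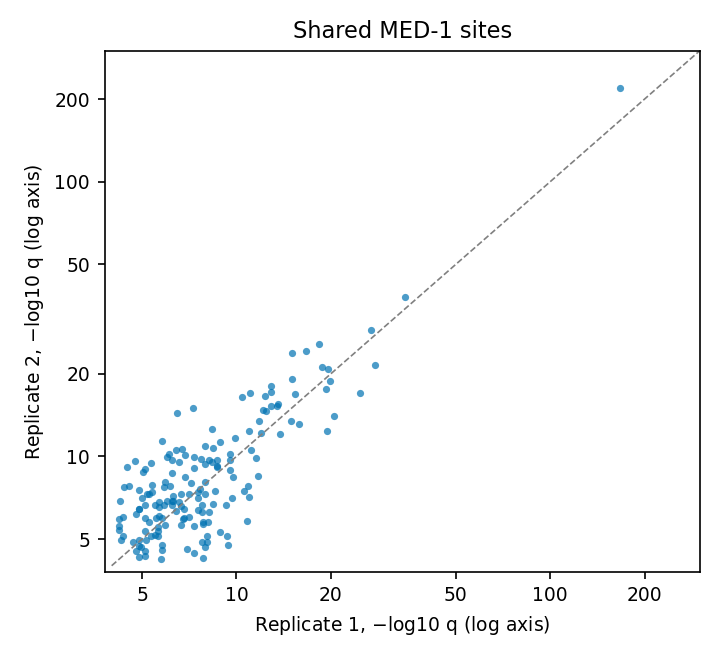
Strength of the 167 sites shared by both replicates, as −log10 of the authors' q-value, with replicate 1 on the x axis and replicate 2 on the y axis (both log axes); each point is 1 site and the dashed line marks equal values. Most sites lie below 20 in both lists, and the strongest region on chromosome I lies far from the rest at 167 and 220.

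The strongest site of all 3 lists was a broad region of 3654 bp on chromosome I, from 15064001 to 15067654 (WS180). Its −log10 q was 271 in the combined list, 167 in replicate 1 and 220 in replicate 2. The second strongest, on chromosome III from 4568524 to 4568891, reached 66.4 in the combined list, 34.4 in replicate 1 and 38.1 in replicate 2. The third lay on chromosome III from 10460975 to 10461387 (combined −log10 q 55.7) and the fourth on X from 11605465 to 11606413 (46.6). The second site of chromosome I ran from 14721444 to 14721804 (45.0), and another chromosome III site from 4170969 to 4171335 (42.5).

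The remaining sites among the 15 strongest had combined −log10 q between 30.8 and 39.4. They were on chromosome I from 1958331 to 1958761 (39.4) and from 14113053 to 14113633 (34.5), and on IV from 11025801 to 11026430 (38.7) and from 390334 to 390699 (36.4). On chromosome III they were the intervals from 5554893 to 5555253 (35.1) and from 3664237 to 3664563 (30.8). Chromosome V held those from 11313980 to 11314477 (34.8) and from 4731410 to 4731747 (30.9), and II the one from 11960536 to 11961083 (31.0). Of the 15, 5 lay on chromosome III, 4 on I, 2 each on IV and V, and 1 each on II and X. All 15 were also the 15 strongest peaks of the combined list, and all ranked within the first 23 sites of replicate 1 and the first 32 of replicate 2. Genes at these positions were not assigned, since the gene table used here is of another genome build.

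The second comparison asked how the combined list relates to the replicates. It contained 207 of the 212 sites of replicate 1 (97.6%, exact interval 94.6 to 99.2%) and 252 of the 258 sites of replicate 2 (97.7%, 95.01 to 99.1%). Of its 599 peaks, 167 overlapped a site in both replicates (27.9%, 24.3 to 31.7%), 40 in replicate 1 only (6.68%, 4.81 to 8.98%) and 85 in replicate 2 only (14.2%, 11.5 to 17.2%). The other 307 overlapped a site in neither list (51.3%, 47.2 to 55.3%).

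The 307 unmatched peaks were weak and narrow. Their median −log10 q was 5.12, against 13.9 for peaks found in both replicates, 7.76 for those in replicate 1 only and 7.58 for those in replicate 2 only. Matched and unmatched peaks differed in median −log10 q by 5.47 and in median width by 89.5 bp (two-sided permutation p = 1e-05 for each). If the combined list rests on the same ChIP samples, as its name says, its strong peaks tend to have a match by design. These differences, and the shares by strength that follow, therefore describe the lists and are no independent support for the matched peaks. The 98 strongest combined peaks all had a match in a replicate. In the strongest 25% of the list 3 of 150 peaks had none, which is 2.00% (exact interval 0.414 to 5.73%), and in the weakest 25% 141 of 149, which is 94.6% (89.7 to 97.7%). All 15 combined peaks shorter than 100 bp, down to 3 bp, were unmatched, and so was the widest, of 5998 bp on X from 12422647 to 12428644.

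**Figure D2:**
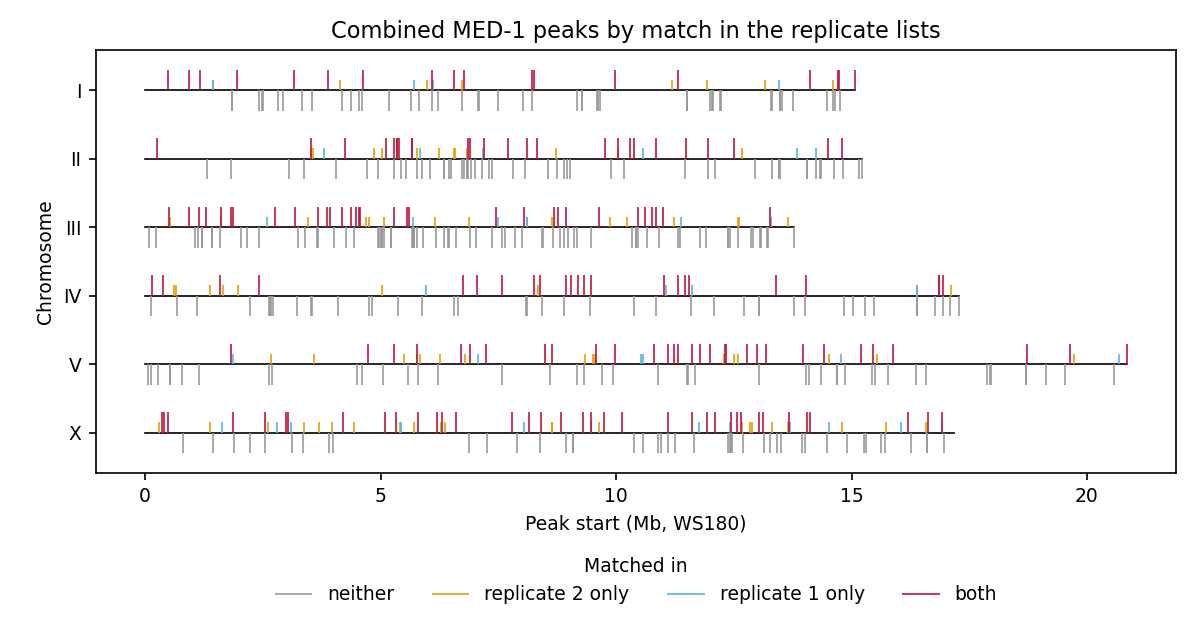
Positions of the 599 combined peaks along the 6 chromosomes (x axis, Mb on WS180), each chromosome drawn from base 1 to the highest peak end. Long ticks above the line are the 167 peaks matched in both replicates, short ticks those matched in 1 replicate, and grey ticks below the line the 307 matched in neither.

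The third comparison asked whether MED-1 peaks were spread evenly over the genome. Chromosome III carried 132 of the 599 combined peaks, 22.04% (exact interval 18.8 to 25.6%), while it makes up 13.9% of the span (exact binomial test, adjusted p = 3.6e-07). That is 9.58 peaks per Mb, against 4.57 on IV and 4.70 on V. The test treats peaks as independent, while some lie close together. The excess on III had a larger adjusted p in the stronger 50% of the list (0.0338, exact binomial test). With peaks less than 50 kb apart merged, a setting chosen after the data were seen, it was 0.00708. Chromosomes IV and V carried fewer peaks than their share, with 13.2% of peaks for 17.4% of the span and 16.4% for 21.0% (adjusted p = 0.0118 for each, exact binomial test). Because the shares add up to the whole list, the excess on III lowers those of the other chromosomes. The tests are thus not independent, and IV and V were not tested with III left out. Neither passed in the stronger 50% of the combined list (adjusted p = 0.114 for each, exact binomial test), nor in 2 settings chosen after the data were seen, peaks with a replicate match (0.0551 on IV and 0.301 on V) and peaks less than 50 kb apart merged (0.231 and 0.249). The counts on I (13.0% of peaks, 15.2% of the span) and II (16.2% and 15.3%) did not pass (adjusted p = 0.231 and 0.57, exact binomial test). Chromosome X carried 19.2% of peaks for 17.3% of the span (adjusted p = 0.257, exact binomial test).

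In the list of each replicate alone, no chromosome passed the adjusted threshold. Chromosome III held 18.9% of sites in replicate 1 (exact binomial p = 0.046, adjusted 0.11) and 19.0% in replicate 2 (p = 0.0238, adjusted 0.0714). The X chromosome held 23.6% in both lists, with an unadjusted exact binomial p of 0.0181 in replicate 1 (adjusted 0.109) and of 0.0104 in replicate 2 (adjusted 0.0624). Among the 292 combined peaks with a replicate match, a split chosen after the data were seen, X carried 24.3% (adjusted p = 0.0146, exact binomial test) and III 19.2% (adjusted p = 0.0327). The lengths behind these shares are approximate.

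**Figure D3:**
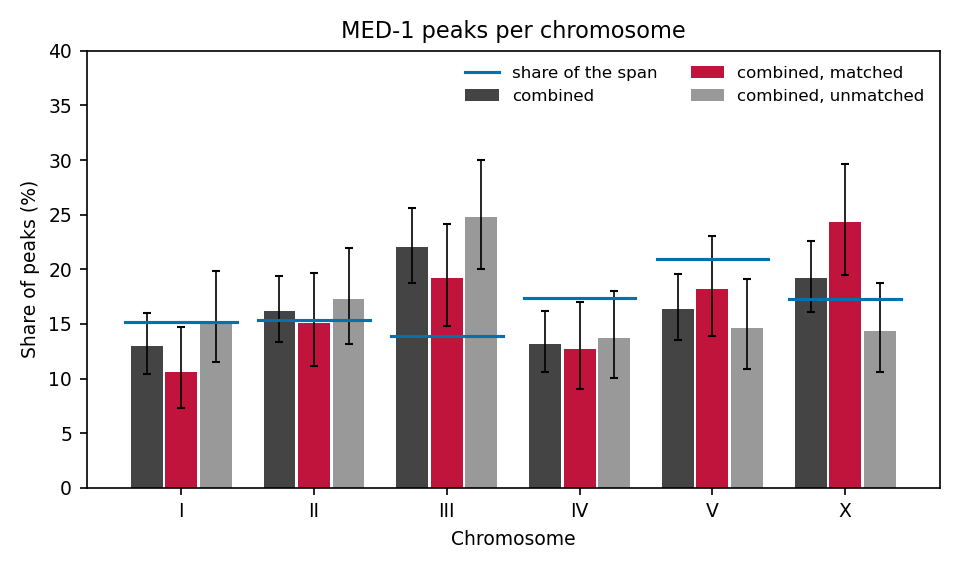
Share of peaks on each chromosome (y axis, %, starting at 0) for all 599 combined peaks, the 292 with a match in a replicate and the 307 without; error bars are 95% exact binomial intervals and blue lines the chromosome's share of the span. Chromosome III stands above its line in all 3 sets. X lies at 24.3% in the matched set, 19.2% in all peaks and 14.3% in the unmatched set, for 17.3% of the span.

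Along the chromosomes, peaks found in a replicate lay more often in the central 50% of the span. This held for 130 of 212 sites of replicate 1 (61.3%, exact interval 54.4 to 67.9%; two-sided permutation p = 0.0011) and 153 of 258 sites of replicate 2 (59.3%, 53.0 to 65.4%; permutation p = 0.0025), where shuffled positions gave 50.0%. In the combined list 324 of 599 peaks were central (54.1%, 50.0 to 58.1%; permutation p = 0.0429), and in its stronger 50% the share was 55.7% and did not pass (permutation p = 0.0507). In a split chosen after the data were seen, the excess was seen in combined peaks with a replicate match, of which 173 of 292 were central (59.2%, 53.4 to 64.9%; permutation p = 0.0023), while 151 of the 307 without a match were (49.2%, 43.5 to 54.9%; permutation p = 0.82). Matched and unmatched peaks differed in this (Fisher's exact test, p = 0.0141, odds ratio 1.502). The replicate lists share 167 sites, and the matched peaks are the combined peaks that overlap sites of those lists. The central shares of these sets are thus not independent of one another. By chromosome, the central share of combined peaks was 66.0% on II and 65.3% on V (exact binomial test, adjusted p = 0.00957 for each over 6 chromosomes). On I, III, IV and X it lay between 44.3% and 53.8% and did not pass (lowest adjusted p = 0.521, exact binomial test). Whether the chromosomes differ from one another in this was not tested.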

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

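Of 62 alternative values for 12 results, 47 kept the direction and the side of the threshold or stayed within the interval, and none reversed a called direction. The 47 include results on chromosomes I, II and X that were not called and stayed so. Another 13 values no longer passed, most of them for the called results on IV and V. The overlap of the replicates, the correlation of their strengths and the greater strength of shared sites passed under each alternative run. As a share of replicate 1, the overlap ranged from 73.6% with the same number of strongest sites from both lists to 78.9% with the lines of replicate 1 as deposited (332 of 421 lines), a setting chosen after seeing the data. As a share of replicate 2, it ranged from 62.0% in the stronger 50% of each list (80 of 129) to 73.6% with equal list length. The share of combined peaks without a match fell to 16.0% in the stronger 50% of the combined list, as those hold the peaks found again. With a list of 1 replicate in place of the combined list, the share on III was 18.9 to 19.0%, on IV 12.8 to 13.7% and on V 17.9 to 18.2%, none past the adjusted threshold, with fewer peaks tested. In the stronger 50%, IV (13.3%) and V (16.7%) no longer passed, and the central share was 55.7% (permutation p = 0.0507). Of the settings added after seeing the data, keeping only peaks with a replicate match gave IV 12.7%, V 18.2% and X 24.3%, with X past the threshold and IV and V not. Merging peaks less than 50 kb apart gave IV 14.04% and V 17.98%, neither past it. The cause was not tested. The excess on III passed in the stronger 50%, in matched peaks and after merging, each with a larger adjusted p than in the full list. The shuffle over promoter windows was not run. No paired analysis was possible because the inputs that share replicate numbers with the ChIP samples have no values of their own in the lists used here. Unknown depth limits what the differing list lengths can show.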

Other observations

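The tests in this part were chosen after the peak lists had been seen. Of the explanations weighed here, only for the merging of chromosome III peaks was the expected outcome set down before the test was run. Expected outcomes for the X share within strength classes and for the doubled lines of replicate 1 were also written and tested, but both were taken out of the record after their results were seen, when this section was shortened. The X test had left its question open, and the doubled lines had been read as against sets of reads called separately. The values for both stand below without a verdict.

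Combined peaks also lay close to one another. Gaps under 10 kb separated neighbouring combined peaks 60 times, against a mean of 38.5 and a central 95% of 28 to 50 in 10000 shuffles within chromosomes (one-sided permutation p = 0.0008). This count was chosen after it had been seen, so it describes the list and decides on no explanation; the outcome written for it, also after the fact, only restated it and was taken out. In the 292 peaks with a replicate match there were 16 such gaps against a shuffled mean of 9.31 (permutation p = 0.0269), and in the single lists 7 against 4.83 and 9 against 7.18 (permutation p = 0.209 and 0.291). The widest combined peak lay in a stretch of X, singled out after its values were seen, where 5 combined peaks between 12416947 and 12458286 covered 12.4 kb of 41.3 kb. Of these, 4 were wider than 1000 bp, out of 17 such peaks in the whole list. The peak from 12444191 to 12446670, of 2480 bp, was found in both replicates, and that from 12416947 to 12418638 in replicate 1 only.

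Chromosome III held 22.04% of combined peaks for 13.9% of the span. A few dense stretches of peaks less than 50 kb apart are argued against as the whole cause. After joining such peaks, 19.7% of the merged stretches (exact interval 15.9 to 23.9%) still lay on III. Broader dense stretches, with peaks farther apart than 50 kb, are not joined by this, so the test cannot decide on those. Peaks without a replicate match are argued against as the whole cause as well, since 19.2% of matched peaks (14.8 to 24.2%) lay there. The margin is thin, as the lower bound is close to 13.9%, and III passed in neither replicate list alone. The matched peaks include 40 found in replicate 1 only and 85 in replicate 2 only. Peaks found in both replicates were not tested on their own for III. Of the unmatched peaks, 76 of 307 lay on III (24.8%, exact binomial test, adjusted p = 2.08e-06). Matched and unmatched shares did not differ past the threshold (Fisher's exact test, adjusted p = 0.23). Unmatched peaks may thus account for part of the excess. The error of the chromosome lengths is also argued against as the whole cause. For the lower bound of its peak share, 18.8%, to equal its share of the length, III would have to run 6.013 Mb beyond its last peak, while the longest gap between neighbouring combined peaks was 0.451 Mb on III and 1.28 Mb on any chromosome. The uneven placement of genes or of open chromatin stays open and was not tested.

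The 307 unmatched peaks may be sites that fell below the threshold in each replicate and passed once the replicates were combined. If strengths add, their combined −log10 q would rarely exceed 8.37, the sum of the lowest values listed in the replicates. This was exceeded by 12 of the 307 (3.91%, exact interval 2.04 to 6.73%), with 5% set as the bound, so the interval leaves the question open. Among the 167 peaks found in both replicates the combined value was a median of 0.945 times the sum of the replicate values and exceeded it in 34.1%. The sum is therefore not a strict limit, and the count above it cannot decide the question.

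The region on chromosome I from 15064001 to 15067654 had a −log10 q 4.09 times that of the next strongest combined peak. The ratio was 4.87 in replicate 1 and 5.78 in replicate 2. These ratios compare significance and not the amount of binding. In the combined list the region was 3654 bp wide, against 368 bp for the next strongest peak. It was the last peak of that chromosome in each list. The ribosomal RNA gene array of C. elegans lies at the right end of this chromosome. DNA present in many copies may give such a region, but this stays open, since read counts of the inputs were not analysed here and genes were not placed on this build.

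The unmatched combined peaks held a smaller share of X than the matched ones, 14.3% against 24.3% (Fisher's exact test, adjusted p = 0.0151 over 6 chromosomes, odds ratio 1.92), a difference of 9.98 percentage points that was 8.62 points within 10 strength classes of about equal size, 9 of which held peaks of both kinds (two-sided permutation p = 0.107 within classes). In replicate 1, 209 of 212 sites were listed in overlapping lines, of which 155 had identical ends and q-values and 194 the same q-value (92.8%, exact interval 88.4 to 95.9%). Where ends differed, in 54 sites, the larger shift was a median of 13 bp.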
